A study of Mus musculus with 24 samples.

How the data were processed

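RNA of sorted mouse cells was measured on 24 oligonucleotide arrays. The labels place the arrays in 10 groups, given by cell population and genetic background. RNA was amplified in 2 rounds for all populations except splenic leukocytes, which had 1 round, per the labels' protocols.

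The values were used as the authors deposited them, in 1 table of linear probe set intensity, with 1 column per array. RMA (robust multi-array average) is named in the submitters' processing notes for 11 of the 24 arrays. For the other 13 arrays, and for the software version and parameters, the processing is not given in the sources used here. The arrays with RMA named include all 3 B6g7 infiltrates and none of the NOD infiltrates, so a difference in processing between those groups cannot be excluded from the notes alone. The median intensity per array ran from 35.1 to 39.1. The smallest deposited intensity was 5.70, with none at or below 0, so log2 was taken without a pseudocount.

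The table held 12488 probe sets, of which 66 controls were left out and 12422 were tested. Probe sets were named from the platform annotation, with symbols updated through Entrez identifiers against the RefSeq gene table of assembly GRCm38.p6. Exactly 1 gene was found for 10833 probe sets, 10817 of them by Entrez identifier. Another 1193 had no gene and 396 had several, and these were tested but not named as genes. For gene lists and named genes, the probe set with the highest mean over all arrays stood for its gene, which left 8251 genes. Where other probe sets of a named gene disagreed in sign, this is stated.

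Group means were fitted to the log2 values of all 24 arrays with limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3, with 14 residual degrees of freedom shared by the 10 groups. The 12 comparisons were adjusted separately by the Benjamini-Hochberg method, and an adjusted p under 0.05 was taken as passing. Every adjusted p of a gene is from this limma fit and is two-sided. Standard errors (SE) are those of the moderated fit. A fold is the antilog of a log2 difference. Fabp1, a liver transcript, lay between 3.22 and 4.36 in the 18 arrays without liver transcripts. Folds of named genes whose lower group mean was at or under 4.36 are given as lower bounds, a rule chosen after seeing the data. This level comes from 1 probe set. The albumin transcript Alb lay between 4.01 and 4.90 in the same arrays, so absent transcripts can also read above 4.36. Folds from lower group means a little above 4.36 may therefore be lower bounds too.

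The lists, groups, comparisons, naming rule and most alternatives were fixed before the data were examined. The naming rule took the 15 largest rises and 15 largest falls among passing genes in the infiltrate comparison, and the 5 largest in each direction elsewhere (10 between T cell sites in NOD). Outside the interactions and the NK comparison with T cells, the arrays of both groups also had to be without overlap. Where under 5 genes passed in a direction, further genes with the smallest p were added up to 5, as values only. A panel of 23 genes was given in the infiltrate comparison whatever its values.

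The 29 gene lists covered cell type markers, immune pathways, cell state and tissues that a pancreatic sample could carry. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjustment ran over the 29 lists within a comparison. For each list the number of members past the threshold over all probe sets and the number adjusted over the list alone were counted. An NK signature was taken from genes at least 2 log2 units higher in NK cells than in both spleen and lymph node T cells, without using the infiltrate arrays. Its mean per array was compared by an exact two-sided permutation test.

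Where groups share replicate numbers, the deviations of same-numbered arrays from their group means were correlated over all probe sets. Pancreatic and lymph node T cells of NOD mice gave 0.34, 0.36 and 0.29 for the 3 pairs, so the numbers were taken to pair those samples. The ages of number 2 differ, at 24 days in the pancreas and 22 in the lymph node, so it may not hold the same mice. The labels do not say what the numbers share.

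Alternatives were quantile normalization, centring on the array median, leaving out the 40% dimmest probe sets, a trended robust prior, array weights, fitting only the compared groups, a replicate block, 1 probe set per gene, runs of adjacent serial codes as a block, and leaving out each array in turn. In the last, a group left with 1 array was assumed to vary like the others. Leaving out arrays with liver transcripts, a liver covariate, leaving out the pancreatic NOD T cell arrays, the serial code block for single genes, all alternatives for the average over populations, leaving out single arrays for the type I interferon list in B6g7 T cells and the estimated correlation as an alternative count of lists were chosen after seeing the data.

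The limma step was tested on simulated data for the infiltrate comparison, with 200 of the 12422 probe sets changed. It recovered 61 of 100 changed by 1 log2 unit and 97 of 100 changed by 2, with 4 false calls among 162. In 8251 simulated genes a list moved by 0.5 was recovered at an adjusted p of 3.22e-23, and 0 of 28 unmoved lists were called by limma's camera. The simulated noise had no correlation between genes and no runs of serial codes or liver transcripts. It therefore cannot show how often unmoved lists or probe sets would be called in the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The number of arrays, 2 or 3 per group, limits the precision.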

Results

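Leukocytes of mice on 2 genetic backgrounds were profiled, with infiltrates and T cells from mice carrying the BDC2.5 T cell receptor transgene, which directs CD4 T cells against the pancreatic islets. On C57Bl/6 with the H2g7 haplotype (B6g7) the labels describe an aggressive islet infiltrate (insulitis), and on NOD a benign one. Total pancreatic infiltrate, sorted as viable CD45-positive cells, was measured in 3 B6g7 and 3 NOD arrays. Clonotype-high CD4 T cells were measured from the pancreas (2 B6g7, 3 NOD) and from the pancreatic lymph node (2 B6g7, 3 NOD). Splenic NK cells and total splenic leukocytes had 2 arrays per background each and served as references; the B6g7 NK cells are labelled as without a transgene, and only NOD NK array 2 is described with BDC2.5. The B6g7 infiltrates were taken at 24, 25 and 28 days of age and the NOD infiltrates at 25 days. B6g7 T cells were taken at 25 and 22 days (arrays 1 and 2) from both sites. NOD T cells were taken at 24, 24 and 25 days from the pancreas and at 24, 22 and 25 days from the lymph node. B6g7 NK cells came from mice of 6 and 3 weeks. No age is given for the NOD NK cells or the splenic leukocytes. The labels do not say whether arrays of a group came from separate animals, so p-values measure only the spread between arrays. The difference between 3′ and 5′ Gapdh control probe sets, a measure of RNA and amplification quality, averaged 0.33 (B6g7) and 0.22 (NOD) log2 units in spleen, 2.96 and 3.32 in infiltrates, 3.67 and 3.85 in pancreatic T cells, 3.33 and 3.05 in lymph node T cells, and 5.13 and 4.65 in NK cells.

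The main comparison set aggressive against benign infiltrates, which also differ in genetic background. Of the genes named from it, Trgv1, Itgae, Ccr2 and Adamdec1 did not pass in an average of the backgrounds over all 5 populations. The other named genes that passed here also passed in that average, which includes the infiltrates. Klra3 and Klrd1, receptors of natural killer (NK) cells, were higher in B6g7 infiltrates. Klra3, of the Ly49 receptor family, rose 3.57-fold (log2 1.84, SE 0.29, adjusted p = 0.00826), from 4.98 ± 0.20 in NOD to 6.82 ± 0.09 in B6g7 (log2, SD, n = 3 each). Klrd1, which encodes the receptor chain CD94, rose 2.93-fold (SE 0.30 on the log2 scale, adjusted p = 0.0359). Trgv1, a variable segment of the T cell receptor gamma chain, rose 5.14-fold (log2 2.36, SE 0.28, adjusted p = 6.28e-04). Itgae, the integrin chain of CD103, rose at least 2.89-fold (SE 0.24, adjusted p = 0.00654), and Ccr2, a chemokine receptor of monocytes and lymphocytes, rose 2.37-fold (SE 0.24, adjusted p = 0.0321). The largest rise was that of Cd72, a B cell surface receptor, at least 6.54-fold (log2 2.71, SE 0.35, adjusted p = 0.00174).

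Single genes of other kinds rose as well. Pdk1, a kinase of pyruvate dehydrogenase, rose 4.36-fold (SE 0.37, adjusted p = 0.0141). Tmem14c, a mitochondrial membrane protein, rose 5.86-fold (adjusted p = 0.0116), and Mff, the mitochondrial fission factor, 4.06-fold (adjusted p = 0.0370). As lists, glycolysis and hypoxia genes (adjusted p = 0.306) and oxidative phosphorylation genes (0.934) did not pass. Smaller rises were those of the predicted gene Gm11346 (at least 3.55-fold), Ly6d (2.77-fold), Hat1 (2.59-fold), Atp6v1d (2.55-fold), Srp9 (2.53-fold) and the amino acid transporter Slc1a5 (2.53-fold), with adjusted p between 0.0268 and 0.0370. A second probe set of Ly6d gave a log2 difference of -0.14, and others of Itgae and Hat1 gave 0.46 and 0.29. The Klra3 probe set belongs to a family of similar sequences and can read related Ly49 genes.

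Among genes lower in B6g7 infiltrates, Emp1, a membrane protein, was 3.99-fold lower (SE 0.28 on the log2 scale, adjusted p = 0.00373). The interferon-activated gene Ifi202b fell by 1.69 on the log2 scale (SE 0.16, adjusted p = 5.77e-05), from 4.85 ± 0.10 in NOD to 3.16 ± 0.34 in B6g7 (n = 3 each). Adamdec1, a metalloprotease of myeloid cells, fell by 1.40 (adjusted p = 0.00462), and Tnfrsf1b, which encodes TNF receptor 2, fell by 1.26 (adjusted p = 0.0301). The next gene, 2810025M15Rik, stood at -0.93 (adjusted p = 0.0581). Ifi202b at 3.16 and Adamdec1 at 4.23 lay in B6g7 at a level where absent transcripts also lie, so their falls are lower bounds.

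**Figure D1:**
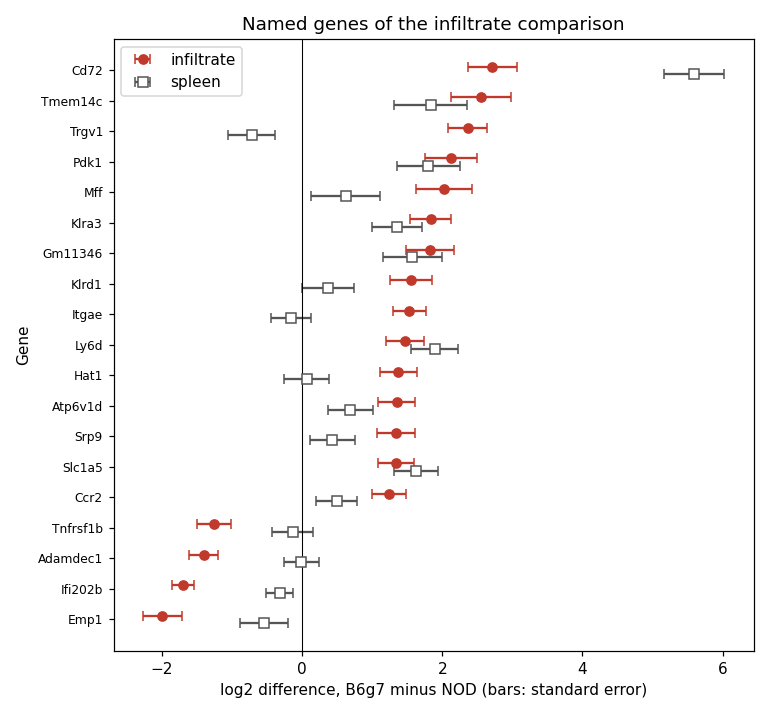
Log2 difference B6g7 minus NOD (horizontal axis, bars are standard errors) of the 19 named genes that passed in the infiltrate comparison, in infiltrates (filled circles, 3 arrays per background) and in splenic leukocytes (open squares, 2 arrays per background). Cd72 was 2.71 in infiltrates and 5.60 in spleen, whereas Trgv1 was 2.36 and -0.72.

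The list of NK receptors and NK lineage genes stood higher in B6g7 infiltrates, with 20 of 23 members above 0 and a mean log2 difference of 0.50 (limma's camera, adjusted p = 8.65e-13, and adjusted p = 0.0833 with an estimated correlation). Klra3 and Klrd1 passed, 21 members did not, and 8 passed when adjusted over the list alone; Klra7 was at 0.98 (adjusted p = 0.129) and Klrg1 at 1.15 (adjusted p = 0.278). The mean of the list per array was 5.88 ± 0.10 in B6g7 and 5.38 ± 0.23 in NOD (log2, SD, n = 3 each, exact permutation p = 0.1, the smallest possible with 3 against 3). Cytotoxic granule and death ligand genes had a mean of 0.42 with 12 of 17 members above 0 (adjusted p = 1.51e-05, and adjusted p = 0.0833 with an estimated correlation). None of the 17 passed over all probe sets and 6 passed when adjusted over the list alone; Gzma was at 1.68 (SE 0.40, adjusted p = 0.122), Gzmb at 1.02, Ctsw at 1.08 and Fasl at 0.98. Interferon-gamma response genes had a mean of 0.21 with 19 of 25 above 0 (adjusted p = 0.0374, and adjusted p = 0.647 with an estimated correlation). No member of that list passed, including Irgm2 at 0.58, Ifi47 at 0.65 and Cxcl9 at 0.50, and 0 passed when adjusted over the list alone. Without the 2 B6g7 infiltrate arrays that carried liver transcripts, which leaves 1 B6g7 array and takes the spread from the other groups, the NK list had an adjusted p of 3.67e-10, the cytotoxic list 1.07e-05 and the interferon-gamma list 0.942, while antigen presentation genes passed as lower (6.38e-04) and dendritic markers as higher (0.0120). With an estimated correlation none of these 5 passed there, at adjusted p of 0.106 (NK, cytotoxic and dendritic), 0.225 (antigen presentation) and 0.990 (interferon-gamma). With serial code runs as a block the 3 lists had 5.20e-10, 3.27e-06 and 0.00138, or 0.125, 0.0713 and 0.290 with an estimated correlation, and cell cycle (0.00101, or 0.844 with an estimated correlation) and tissue homing genes (0.00488, or 0.650) also passed.

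Of the fixed panel of 23 genes, 19 had a probe set and Klrd1 alone passed over all probe sets, while 6 passed when adjusted over the panel alone. Ifng, the main cytokine of NK and T helper 1 cells, was at 1.43 (SE 0.40, adjusted p = 0.278), Ccl5 at 1.41, Prf1 at 0.80 and Klrk1 at 0.79. The T cell genes Cd3e, Cd4 and Cd8a were at -0.10, -0.19 and 0.25, and the B cell gene Cd79a at -0.27. The myeloid genes Itgam and Adgre1 were at 0.11 and -0.72. Tnf (0.03), Il10 (0.15), Il4 (-0.42), Il2rb (0.25), Ctla4 (0.35) and Ncr1 (0.19) had adjusted p of 0.999. Itgam and Il4 in both backgrounds and Ncr1 in NOD lay at a level where absent transcripts also lie, so these differences are not measured exactly. Klrb1c, Nkg7 and Foxp3 were among those without a probe set of a single gene.

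A signature of 28 genes taken from the NK arrays was at 6.44 ± 0.16 in B6g7 and 6.07 ± 0.28 in NOD infiltrates (mean log2, SD, n = 3 each), a 1.29-fold difference (log2 0.37) with an exact permutation p of 0.2. The difference was 0.12 with members at least 1 log2 unit higher in NK cells, 0.13 with members chosen against T cells alone and 0.22 without NOD array 2. Of its members 20 were higher, and Klra3, Klrd1 and Ccr2 passed. When adjusted over the signature alone, 11 passed, 8 of them higher; Spic (-0.74), Cadm1 (-0.78) and Slc12a2 (-0.91) were lower. Against all genes, limma's camera gave p = 2.88e-08, with p = 0.00519 at an estimated correlation. The signature shared 6 genes with the NK list, and 6 of its genes belonged to lists other than the NK and cytotoxic lists. Among these were Mrc1 and Ccr2 of the macrophage list and Mki67 of the cell cycle list. The NK arrays also carried granulocyte transcripts, with S100a8 at 5.03 in NOD NK array 1 and 12.58 in NOD NK array 2. The signature is therefore not a measure of NK cell content alone. Its difference between backgrounds was 0.13 in spleen, 0.26 in NK cells, -0.19 in pancreatic T cells and 0.07 in lymph node T cells.

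**Figure D2:**
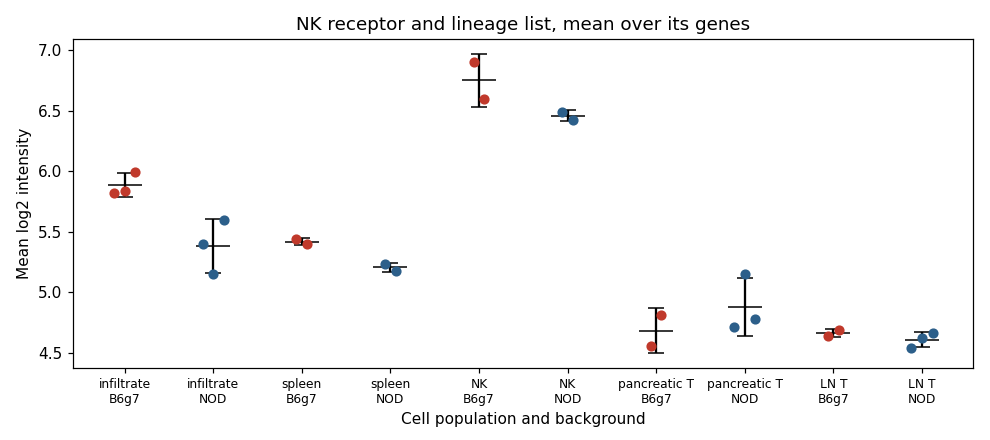
Mean log2 intensity of the 23 genes of the NK list (vertical axis) in each of the 24 arrays (points), by group, with group mean and SD (bars). B6g7 infiltrates lie at 5.88 ± 0.10 and NOD infiltrates at 5.38 ± 0.23.

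In all, 34 probe sets passed between infiltrates, 27 higher and 7 lower in B6g7, and 521 had an unadjusted p under 0.05. With only the compared groups fitted 29 passed, of which 14 were among the 34. With array weights 302 passed, 152 higher and 150 lower. B6g7 array 2, which carried liver transcripts, then had a weight of 6.078, against 0.588 and 0.601 for B6g7 arrays 1 and 3. The weighted B6g7 values thus rest mostly on 1 array. With a liver covariate 46 passed, 36 higher and 10 lower. Of these 30 were among the 34, and all 34 kept their sign. Of the 34, 28 matched exactly 1 gene. By the probe set that stood for each gene, 23 genes passed, 19 higher and 4 lower. Serial codes in the descriptions fell into 3 runs, and with the run as a block 15 probe sets passed, 14 of them among the 34. All 34 kept their sign in the block and in both runs that held both backgrounds. The 34 were called from these same arrays, so their kept signs are no separate support. For the named genes, the rule of no overlap between backgrounds fixes the sign within each run. Cd72, Trgv1, Ly6d, Slc1a5, Itgae, Ifi202b, Emp1 and Adamdec1 passed with the block, while Klra3 (adjusted p = 0.0788), Klrd1 (0.0799), Ccr2 (0.0552), Pdk1 (0.0949), Tmem14c (0.0523), Srp9 (0.0523), Tnfrsf1b (0.0704), Hat1 (0.190), Atp6v1d (0.191), Mff (0.219) and Gm11346 (0.239) did not. The mean of the NK list was 0.48 with the block and 0.54 and 0.40 within the runs, that of the cytotoxic list 0.44, 0.56 and 0.28, that of the interferon-gamma list 0.29, 0.42 and 0.11, and that of the signature 0.38, 0.44 and 0.30. Cd72, Trgv1, Itgae, Emp1, Ifi202b and Adamdec1 passed whichever array was left out. The others were lost in at least 1 case. Without NOD array 1, Klra3 had an adjusted p of 0.0574, Pdk1 0.122, Slc1a5 0.164, Gm11346 0.193, Tnfrsf1b 0.204, Hat1 0.210 and Atp6v1d 0.229. Without NOD array 2, Klrd1 had 0.220, Ccr2 0.184 and Mff 0.184, and without B6g7 array 1, Tmem14c had 0.0859, Ly6d 0.121 and Srp9 0.221. The count fell to 2 without the 2 B6g7 arrays with liver transcripts, to 16 without B6g7 array 1 or NOD array 1, to 17 without B6g7 array 2 and to 18 without NOD array 2.

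Splenic leukocytes of the same backgrounds served as the reference population. Cd72 was at least 48.4-fold higher in B6g7 spleen (log2 5.60, SE 0.43, adjusted p = 3.35e-06), at 8.98 ± 0.28 against 3.38 ± 0.25 in NOD (n = 2 each), where it did not stand above the level of absent transcripts. Ifi209, an interferon-inducible gene of the family of Ifi202b, rose 3.82-fold (adjusted p = 6.31e-04), and Ly6d, a marker of B cell precursors, 3.72-fold (adjusted p = 0.0383). The immunoglobulin kappa segment Igkv15-103 fell by 1.95 on the log2 scale (adjusted p = 0.0114), and Cap1, an actin regulator, fell by 1.77 (adjusted p = 6.78e-04). Slc1a5 was at 1.63 (adjusted p = 0.0812), Igkv8-30 at 2.03, Notch4 at -0.79, Fcrla at -1.37 and Trib3 at -0.54; another probe set of Igkv8-30 was at -0.06. Of the infiltrate genes, Klra3 was at 1.35 (adjusted p = 0.601), Klrd1 at 0.37, Itgae at -0.16 and Ccr2 at 0.49 in spleen.

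B cell markers stood higher in B6g7 spleen, 16 of 20 above 0 and Cd72 alone passing over all probe sets and when adjusted over the list alone (adjusted p = 2.47e-09, and adjusted p = 0.0810 with an estimated correlation). Vpreb3 (0.83) and Spib (0.71) did not pass. The NK list had 17 of 23 members above 0 (adjusted p = 6.47e-04, and adjusted p = 0.469 with an estimated correlation), with 1 member passing when adjusted over the list alone. Lower were interferon-gamma response genes (adjusted p = 2.34e-05; Gbp2 at -0.85, Igtp at -0.72), T cell markers (adjusted p = 2.34e-05; Cd3g at -0.88, Cd27 at -0.60), T cell activation genes (adjusted p = 0.00145) and negative regulators (adjusted p = 0.0476), with 0 members passing over all probe sets or when adjusted over the list alone. With an estimated correlation these 4 had adjusted p between 0.139 and 0.308. Cd8b1, a T cell marker, was at 2.25, against the direction of its list.

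Between spleens 9 probe sets passed, 5 higher and 4 lower (155 at an unadjusted p under 0.05). The share higher was 55.6%, and 45.5% of the 11 calls after quantile normalization. Cd72, Ifi209 and Cap1 passed whichever array was left out; without NOD array 2, Ly6d had an adjusted p of 0.937 and Igkv15-103 of 0.415.

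The interaction asked which differences between backgrounds were unlike in infiltrate and spleen. Trgv1 differed by 3.08 log2 units (SE 0.44, adjusted p = 0.0124), being higher in B6g7 infiltrates (2.36) and at -0.72 in spleen. Ifi209 differed by -2.05 (SE 0.28, adjusted p = 0.0124), with 1.93 in spleen and -0.11 in infiltrates. Ifi202b was at -1.38 (adjusted p = 0.0703), Cd72 at -2.89 and Cap1 at 1.48 (both adjusted p = 0.107), Itgae at 1.69 (adjusted p = 0.405), Adamdec1 at -1.39 (adjusted p = 0.527), and Trgv4 (1.43), Fam189b (0.93) and Cd93 (-2.39) at 0.999. Of these, Ifi202b, Itgae and Adamdec1 lay at a level where absent transcripts also lie in 3 of the 4 groups, Cd72 and Cap1 in 2 and Trgv4 in 1, so their interactions are not measured exactly. For Ifng, at the level of absent transcripts in both spleen groups, the interaction was 1.59 (adjusted p = 0.999), and for Klrd1 1.18 (adjusted p = 0.999). For Klra3 it was 0.48 (adjusted p = 0.999), so neither Klra3 nor Klrd1 was shown to differ between infiltrate and spleen.

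As lists, 8 stood higher and 2 lower in the interaction by limma's camera. Interferon-gamma response genes had 22 of 25 above 0 (mean 0.44, adjusted p = 1.26e-06, and adjusted p = 0.0891 with an estimated correlation), among them Igtp at 1.11 and Gbp2 at 1.01. The NK list had 18 of 23 above 0 (mean 0.29, adjusted p = 2.55e-05, and adjusted p = 0.247 with an estimated correlation), with Cd244a at 1.01. T cell markers had 16 of 17 (adjusted p = 3.92e-05), with Cd3d at 1.22. Cytotoxic genes (0.00191), T cell activation (0.00189), negative regulators (0.00301), tissue homing (0.00505) and cell cycle genes (0.0213) were higher, and B cell markers (1.82e-05; Vpreb3 at -1.11) and granulocyte markers (0.0450; S100a9 at -2.14) lower. With an estimated correlation, the adjusted p of the 8 lists other than the NK and interferon-gamma lists lay between 0.0751 and 0.627. Adjusted over the list alone, 2 B cell markers and 1 tissue homing gene passed, and no member of any list passed over all probe sets.

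In the interaction 5 probe sets passed, 3 higher and 2 lower (149 at an unadjusted p under 0.05). Trgv1 had an adjusted p of 0.145 without NOD spleen array 1 and Ifi209 of 0.0968 without NOD spleen array 2. The count was 0 without NOD spleen array 1 or B6g7 spleen array 2, 1 without B6g7 spleen array 1, 2 without NOD spleen array 2, and 3 without infiltrate array 3 of either background.

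Clonotype-high T cells from the pancreas were compared between backgrounds next. Gm11346 rose at least 9.87-fold in B6g7 (log2 3.30, SE 0.39, adjusted p = 0.00190), Pdk1 7.19-fold (SE 0.41, adjusted p = 0.00556) and Myo6, an actin motor, 3.93-fold (adjusted p = 0.00556). Akap9, a scaffold protein of the centrosome and Golgi, rose at least 3.88-fold (adjusted p = 0.0132), and Runx1, a transcription factor of T cell development, at least 2.66-fold (adjusted p = 0.00556). Irf8, an interferon-regulated transcription factor, fell by 2.13 on the log2 scale (SE 0.31, adjusted p = 0.00556), at 6.34 ± 0.15 (n = 2) against 8.47 ± 0.64 (n = 3). Tnfrsf1b fell by 1.48 (adjusted p = 0.0300), the stress gene Gadd45b fell by 1.24 (adjusted p = 0.0260) and Strap fell by 0.82 (adjusted p = 0.0374). Ybx3 was at -1.06 (adjusted p = 0.107).

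Activation genes stood lower in B6g7 pancreatic T cells, with 4 of 26 above 0 (limma's camera, adjusted p = 8.49e-08, and adjusted p = 0.05002 with an estimated correlation). Tnfrsf4, which encodes OX40, was at -1.27, Irf4 at -1.29 and Cd83 at -1.21, and 6 members passed when adjusted over the list alone. Regulatory T cell markers had 1 of 17 above 0 (adjusted p = 1.40e-05, and adjusted p = 0.05002 with an estimated correlation), with Nrp1 at -1.17 and 3 passing over the list alone. Naive T cell genes stood higher, with 10 of 11 above 0 (adjusted p = 1.75e-06, and adjusted p = 0.05002 with an estimated correlation), among them Il7r (1.46) and Foxp1 (1.18), and 3 passed when adjusted over the list alone. Type I interferon genes had 14 of 16 above 0 (adjusted p = 8.49e-08, and adjusted p = 0.0914 with an estimated correlation), with Ifit1 at 1.79, Ifit2 at 1.74 and Usp18 at 1.79, and 5 passing over the list alone. Ifit1 was at 8.08 in B6g7 array 1 and 5.65 in array 2. The interferon-gamma list was higher (adjusted p = 0.0255, and adjusted p = 0.312 with an estimated correlation), although Irf8, its member that passed, fell. Igtp was at 1.54, and 3 members passed when adjusted over the list alone.

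Cell cycle genes were lower, with 4 of 37 above 0 (adjusted p = 5.57e-06; Mki67 at -1.17, Mcm3 at -1.09). Lower as well were glycolysis genes (adjusted p = 0.0108), in which Pdk1 went the opposite way, tissue homing genes (0.0114; Itgb1 at -1.37), fibroblast and endothelial genes (0.0122), chemokines (0.0319) and the NK list (0.0443; Eomes at -1.46). Acinar genes of the exocrine pancreas (adjusted p = 1.10e-05; Prss2 at 2.18) and ribosomal proteins (0.00285; Rps3 at 0.80) were higher. The adjusted p of these 8 lists with an estimated correlation lay between 0.213 and 0.497. Adjusted over the list alone, 4 tissue homing, 2 NK, 1 acinar and 1 glycolysis gene passed. Alb, a liver gene, was at 12.06 and 4.57 in the B6g7 arrays and at 12.71, 4.90 and 4.35 in the NOD arrays, and Prss2 at 9.21 in B6g7 array 1. The Gapdh 3′ to 5′ difference varied with an SD of 1.05 over the NOD and 0.06 over the B6g7 arrays.

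Of the 18 probe sets passing in pancreatic T cells, 12 were higher and 6 lower (800 at an unadjusted p under 0.05). With replicate number as a block 307 passed, 144 higher and 163 lower. None of the 9 named genes passed with each array left out. Without B6g7 array 1 the adjusted p was 0.0523 for Gm11346, 0.131 for Pdk1 and Irf8, 0.202 for Gadd45b, 0.230 for Tnfrsf1b, 0.232 for Runx1 and 0.395 for Akap9 and Strap; without B6g7 array 2 it was 0.0835 for Myo6. The count was 3 without B6g7 array 1, 40 without NOD array 2 and 119 without NOD array 3. It was 0 when only the compared groups were fitted or arrays were weighted, and 3 without the arrays with liver transcripts.

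In T cells of the pancreatic lymph node, Pdk1 rose 6.22-fold in B6g7 (SE 0.41, adjusted p = 0.00910) and Gm11346 6.20-fold (adjusted p = 0.00655). Ly6e, an interferon-inducible surface protein, rose 4.22-fold (adjusted p = 0.00908), although another probe set was at -0.29. Akap9 rose at least 3.79-fold (adjusted p = 0.0148) and Myo6 3.31-fold (adjusted p = 0.0142). Hars, the histidyl-tRNA synthetase, fell by 2.22 on the log2 scale (SE 0.37, adjusted p = 0.0156), and the receptor gene Tlr6 fell by 1.23 (adjusted p = 0.00921). Ryr2, a calcium channel, fell by 1.16, Scg5 fell by 1.14 and Frg1 fell by 1.13 (adjusted p = 0.00655, 0.00421 and 0.0489). Ryr2 (3.46) and Scg5 (3.51) lay in B6g7 at the level of absent transcripts, so their falls are lower bounds.

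T cell activation genes were lower in B6g7 lymph node T cells, with 7 of 26 above 0 (adjusted p = 0.00305, and adjusted p = 0.803 with an estimated correlation). Tnfrsf18 was at -1.23 and Tnfsf11 at -1.22, and 2 members passed when adjusted over the list alone. Acinar genes were higher (21 of 23, adjusted p = 8.13e-05; Prss2 at 2.23, Cel at 0.76), as were fibroblast and endothelial genes (21 of 24, adjusted p = 0.0276; Dcn at 1.38); both had an adjusted p of 0.803 with an estimated correlation, and 2 acinar genes passed over the list alone. In B6g7 array 1 Prss2 was at 8.46 and Alb at 11.71, against 4.05 and 4.41 in array 2.

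Of 16 passing probe sets 9 were higher and 7 lower (864 at an unadjusted p under 0.05), and none of the 10 named genes passed with each array left out. Without B6g7 array 1 the adjusted p was 0.111 for Scg5, 0.137 for Ryr2, 0.142 for Ly6e, 0.145 for Myo6, 0.279 for Gm11346 and Hars, 0.351 for Tlr6, 0.620 for Akap9 and 0.799 for Frg1; without B6g7 array 2 it was 0.118 for Pdk1. The count was 1 without B6g7 array 1, 2 without B6g7 array 2, 8 without NOD array 1, and 2 when only the compared groups were fitted.

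Within B6g7, T cells of the pancreas were set against those of the lymph node. No probe set passed by limma, and 81 had an unadjusted p under 0.05. Type I interferon genes as a list stood higher in the pancreas, with 14 of 16 above 0 and a mean of 0.73 (limma's camera, adjusted p = 1.13e-14, and adjusted p = 0.0439 with an estimated correlation). Ifit1 was at 1.77, Usp18 2.83-fold higher, Ifit3 at 1.42 and Mx1 at 1.16, and 0 members passed when adjusted over the list alone. Pancreas array 1 carried most of this, with a list mean of 6.84 against 6.05 in array 2 and Ifit1 at 8.08 against 5.65. Without pancreas array 2 the list had a mean difference of 1.13. Without pancreas array 1 the list had a mean difference of 0.33 and did not pass (adjusted p = 0.234, and 0.888 with an estimated correlation). Without lymph node array 1 or 2 it passed at the preset correlation and had an adjusted p of 0.612 or 0.127 with an estimated correlation. Acinar genes (22 of 23, adjusted p = 2.97e-05; Sycn at 0.59), T helper cytokines (20 of 23, adjusted p = 0.00534; Ifng at 1.26) and tissue homing genes (adjusted p = 0.0452; S100a4 at 0.75) were higher, and cell cycle genes lower (5 of 37 above 0, adjusted p = 3.26e-05; Stmn1 at -0.95). With an estimated correlation the adjusted p of these 4 lists lay between 0.784 and 0.791, and 0 members passed over the list alone. The genes with the smallest p were Mat1a (0.45), Crabp1 (0.56), Irf7 (0.99), Plac8 (0.84), Nefh (-0.65), Tspan13 (-1.01), Irf4 (-1.27), Mrps2 (-0.50) and Synj2 (-0.46), each with an adjusted p of 0.9999.

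Within NOD, BC147527 fell by 1.32 in the pancreas (SE 0.19, adjusted p = 0.0331) and Scg5, a secretory granule protein, fell by 0.91 (SE 0.14, adjusted p = 0.0380) to 3.74, a level where absent transcripts also lie. The regulatory cytokine Il10 was at 0.59 (adjusted p = 0.0913), Gstm3 at 0.61, Gnas at 0.78, Mast2 at 0.64 and Cyp8b1 at 0.83, and Krt10 (-1.04, adjusted p = 0.0527), Map4k4 (-1.56) and Ezh1 (-0.65) were lower without passing. Other probe sets were at -0.02 and -0.12 for Gnas, 0.54 for Krt10 and -0.58 and 0.00 for Map4k4. Fibroblast and endothelial genes stood higher in the pancreas (23 of 24 above 0, adjusted p = 1.26e-04, and adjusted p = 0.684 with an estimated correlation), with Fn1 at 1.43 and Bgn at 0.95. Chemokines were higher (20 of 25, adjusted p = 0.0304; Ccl5 at 2.47, Ccl1 at 1.02; 3 passing over the list alone), as were regulatory T cell markers (14 of 17; Nrp1 at 1.73, Tnfrsf4 at 1.20; 4 over the list alone), the NK list (22 of 23; Klrg1 at 1.25; 1 over the list alone), macrophage markers (24 of 27; Apoe at 2.13) and acinar genes (22 of 23; Amy1 at 1.70), each of the latter 4 at an adjusted p of 0.0373. Interferon-gamma genes were lower (8 of 25 above 0, adjusted p = 0.0387; Irf1 at -1.33, Psmb9 at -1.19; 3 passing over the list alone). For these 6 lists the adjusted p was between 0.708 and 0.735 with an estimated correlation. Alb, at 12.71 in NOD pancreas array 1, moved with Apoe, which liver also expresses.

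Of 2 probe sets passing in NOD, both were lower, while 2263 had an unadjusted p under 0.05. Pancreas arrays 1 and 2 stood apart, correlating at 0.82 with each other and at 0.85 and 0.88 with array 3, and carried weights of 0.214 and 0.148 when arrays were weighted. Pancreas array 3 correlated at 0.993 with lymph node array 3, the highest value of any pair of arrays. It thus stood closer to that lymph node array than to the other pancreas arrays. The Gapdh 3′ to 5′ difference was 3.91, 4.87 and 2.78 in the pancreas arrays and 2.93, 3.09 and 3.12 in the lymph node arrays. For the genes and lists above, RNA quality thus moved with site in pancreas arrays 1 and 2, while array 3 lay below every lymph node array. Without lymph node array 1 both genes had an adjusted p of 0.212. The count was 0 without lymph node array 1 or 2 or pancreas array 1 or 2, 36 without lymph node array 3 and 1849 without pancreas array 3. It was also 0 with array weights or with only the compared groups.

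The difference between the site effects of the backgrounds gave no passing probe set by limma (351 at an unadjusted p under 0.05); without NOD lymph node array 3, 1 passed. Type I interferon genes differed as a list (13 of 16 above 0, mean 1.08, adjusted p = 1.28e-08, and adjusted p = 0.273 with an estimated correlation), with Ifit1 at 2.42, Ifit3 at 2.23 and Usp18 at 2.19, and 9 members passed when adjusted over the list alone, again with B6g7 pancreas array 1 well above array 2. Interferon-gamma genes (18 of 25, adjusted p = 0.00110; Igtp at 2.13; 2 over the list alone) and naive T cell genes (10 of 11, adjusted p = 0.00842; Foxp1 at 1.07) were higher. Fibroblast and endothelial genes (adjusted p = 2.82e-05; Bgn at -1.13), regulatory T cell markers (0.00842; Nrp1 at -1.33), chemokines (0.0158; Ccl5 at -1.75) and the NK list (0.0386; Klrg1 at -1.12) were lower. The adjusted p of these 6 lists with an estimated correlation lay between 0.286 and 0.748. Single genes with the smallest p were BC147527 (1.59, adjusted p = 0.832), Scg5 (0.87, at a level where absent transcripts also lie in 3 groups), Ezh1 (0.76), Maf1 (1.29), Gstm3 (-0.79), Irf8 (-1.49), Nefh (-0.71), Foxa1 (-0.80, at that level in all 4 groups) and Myh7 (-0.61).

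Splenic NK cells differed between backgrounds most in Klrb1a, an NK receptor of the NKR-P1 family, which rose 9.64-fold in B6g7 (log2 3.27, SE 0.36, adjusted p = 7.77e-04), at 7.97 ± 0.44 against 4.70 ± 0.14 (n = 2 each). The NOD mean lay within the range of Alb in arrays without liver transcripts (4.01 to 4.90), so this fold may be a lower bound. Khdc1c rose 3.37-fold and Agtrap 2.22-fold (both adjusted p = 0.0223). Epb41l4aos was at 2.11, Pla2g12a at 2.19, Emp1 at -1.84 and Igkv6-23 at -1.48 (adjusted p = 0.0726), with another Pla2g12a probe set at -0.41; Eloa (-0.74), Stx3 (-0.96) and Ifi202b (-0.74) had larger p, and another probe set of Eloa was at 0.12. The NK list was higher in B6g7 (15 of 23, adjusted p = 1.57e-05; Klrb1a alone passing, also over the list alone), although Klrb1b was at -0.82, as were cytotoxic genes (12 of 17, adjusted p = 0.00586; Gzmb at 1.10). Antigen presentation genes were lower (3 of 15 above 0, adjusted p = 1.41e-06; H2-Aa at -1.01, Cd74 at -1.22), as were plasma cell markers (adjusted p = 3.47e-05; Igha at -2.31) and B cell markers (adjusted p = 0.00111; Ighm at -0.74), with 0 passing over the list alone in these 4 lists. With an estimated correlation all 5 lists had adjusted p between 0.0621 and 0.310. The granulocyte gene S100a8 was at 9.04 and 11.29 in B6g7 and at 5.03 and 12.58 in NOD arrays.

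In NK cells 6 probe sets passed, 4 higher and 2 lower (156 at an unadjusted p under 0.05). Without B6g7 array 1 Khdc1c had an adjusted p of 0.330 and Agtrap of 0.324; Klrb1a passed in each case. The count was 3 without B6g7 array 1, 13 without NOD array 1 and 0 with only the compared groups. NOD array 2 is described with the BDC2.5 transgene and array 1 is not.

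Infiltrates were also compared with spleen of the same background. Il1rn, the interleukin-1 receptor antagonist, was at least 16.3-fold higher in B6g7 (log2 4.03, SE 0.38, adjusted p = 1.81e-06) and at least 16.4-fold in NOD (adjusted p = 1.73e-06). Cxcl9, a chemokine induced by interferon-gamma, was at least 10.7-fold and 7.90-fold higher, and the acute phase gene Saa3 at least 8.45-fold (adjusted p = 0.00420) and 13.1-fold (adjusted p = 8.40e-04). In spleen these genes lay between 3.76 and 4.29, where absent transcripts also lie. Trgv1 (11.9-fold) and Ifng (at least 7.93-fold, from 3.18, adjusted p = 3.71e-04) rose in B6g7, and App (14.7-fold) and Cd93 (8.76-fold) in NOD. Tmsb10, an actin-binding protein, fell by 5.17 and by 5.12 on the log2 scale. Immunoglobulin segments fell in both: Ighv14-2 was at -4.57 and -4.78 and a kappa segment of the Igkv1 family at -4.07 and -4.78, the latter down to 3.47, where absent transcripts also lie. An Igkv9 segment (-4.24) and Ighv1-54 (-4.08) followed in NOD, although other probe sets of that Igkv9 segment were at 0.07 and 0.16. Cd79a (-3.81) and H2-DMb2 (-3.63) completed the B6g7 genes.

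B cell markers were lower in infiltrates of both backgrounds, with 15 of 20 passing in B6g7 and 13 in NOD (19 and 15 over the list alone, and adjusted p = 4.95e-23 and 8.24e-16, and adjusted p = 0.00158 and 0.00959 with an estimated correlation). Vpreb3 was at -3.34 and -2.23, and Cd74 at -3.44 and -3.17. Antigen presentation genes fell (7 of 15 passing in each, 8 over the list alone, and adjusted p = 2.04e-08 and 1.44e-08, and adjusted p = 0.0687 and 0.0648 with an estimated correlation), as did ribosomal proteins (5 and 8 of 26 passing, 11 over the list alone in each; Rps7 at -2.53 and -2.90, and adjusted p = 3.02e-05 and 2.27e-06, and adjusted p = 0.0687 and 0.0493 with an estimated correlation). Macrophage markers rose (6 and 10 of 27 passing higher, 2 and 1 lower; 10 and 14 over the list alone; Msr1 at 1.88 and 2.52, Mpeg1 at 1.95 and 2.65), as did chemokines (5 and 6 of 25 higher, with 1 lower in NOD; 7 over the list alone in each; Ccl3 at 1.49 in B6g7, Cxcl2 at 1.21 in NOD). Cell cycle genes were higher in both (Cdk1 at 1.43 and 1.11), with 3 and 0 of 37 passing, also over the list alone. In NOD, T cell markers were lower (2 of 17 passing, also over the list alone; Cd3d at -1.95). Adjusted p of these lists ran from 4.13e-05 to 0.0478, and from 0.257 to 0.771 with an estimated correlation.

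In B6g7 the NK list (5 higher and 1 lower of 23; Klrg1 at 2.38, Cd244a at 1.91), cytotoxic genes (2 of 17; Gzmb 5.65-fold higher, Fasl at 1.63), interferon-gamma genes (4 higher, 1 lower of 25; Irgm2 at 1.92), activation genes (2 higher, 1 lower of 26; Socs2 at 1.60) and tissue homing genes (9 higher, 1 lower of 25; Ahnak at 2.33) were also higher, with adjusted p from 0.00147 to 0.0251. Adjusted over the list alone, 7, 5, 10, 3 and 13 members of these lists passed, and their adjusted p with an estimated correlation lay between 0.219 and 0.459. In all 942 probe sets passed in B6g7 (366 higher, 576 lower) and 1133 in NOD (480 higher, 653 lower). Spleen RNA had 1 amplification round and infiltrate RNA 2, so site and amplification cannot be told apart, and the Gapdh 3′ to 5′ difference moved with site. The titles of the spleen arrays name no BDC2.5 transgene, and no age is given for them. Xist, expressed in female cells, lay between 3.40 and 3.55 in spleen arrays and between 3.72 and 7.56 in infiltrates. Transgene, age and sex may therefore differ with site as well. Saa3 in B6g7 had an adjusted p of 0.0587 without spleen array 1. The counts were 324 and 396 without B6g7 spleen array 1 or 2, 625 without B6g7 infiltrate array 3, and 351 and 453 without NOD spleen array 1 or 2.

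Splenic NK cells differed from lymph node T cells in 1882 probe sets, 804 higher and 1078 lower in NK cells. RNA quality moved with this comparison, with Gapdh 3′ to 5′ differences of 5.13 and 4.65 in NK cells and 3.33 and 3.05 in T cells, and actin differences of 5.47 and 5.40 against 2.73 and 2.21. Xist lay between 3.71 and 3.83 in NK arrays. In lymph node T cells it was at 6.09 and 7.29 (B6g7) and at 3.64, 6.92 and 6.81 (NOD), so sex may differ as well. Tyrobp, an adaptor of NK receptors, was at least 91.1-fold higher (log2 6.51, SE 0.41, adjusted p = 9.46e-09), Ccl5 37.3-fold and Anxa1 at least 73.5-fold. The granulocyte genes S100a9 (at least 40.1-fold) and S100a8 (33.3-fold) were higher on average, but at least 11.6-fold and 8.99-fold without NOD NK array 2, and at least 139-fold and 123-fold without NOD NK array 1. Cd3d, of the T cell receptor complex, fell by 3.89 on the log2 scale (another probe set at -0.19), Dgka fell by 3.56, Uqcrh fell by 3.30, Rps7 fell by 3.19 and Sf3b1 fell by 3.02; each of the 10 passed whichever array was left out. The NK list had 18 of 23 passing, all higher (19 over the list alone; Klra3 at 4.98, and adjusted p = 1.33e-22, and adjusted p = 0.0119 with an estimated correlation). Cytotoxic genes had 9 of 17 (10 over the list alone; Gzma at 3.40), dendritic markers 5 higher and 1 lower of 18 (8; Id2 at 3.66) and B cell markers 12 of 20 (12; Blk at 3.78), with adjusted p of 3e-07, 0.00188 and 2.41e-09, and all 3 at an adjusted p of 0.0243 with an estimated correlation.

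Higher in NK cells by limma's camera were also macrophage markers (16 of 27 passing, 20 over the list alone; Csf1r at 3.11), granulocyte markers (9 of 23, 11 over the list alone), antigen presentation (6 of 15, 6 over the list alone; H2-Aa at 3.62), erythroid genes (5 of 12, 7 over the list alone; Ank1 at 1.56), tissue homing genes (10 of 25, 15 over the list alone; Vcam1 at 4.93), cell cycle genes (13 higher, 2 lower of 37, 18 over the list alone; Mki67 at 2.17) and chemokines (3 higher, 1 lower of 25, 4 over the list alone). Lower were T cell markers (8 of 17, 13 over the list alone; Cd3g at -2.60), interferon-gamma genes (7 lower, 1 higher of 25, 13 over the list alone; Psmb9 at -2.18), ribosomal proteins (9 lower, 1 higher of 26, 14 over the list alone), activation genes (8 lower, 2 higher of 26, 14 over the list alone; Irf4 at -2.25), negative regulators (5 lower, 1 higher of 18, 9 over the list alone; Ctla4 at -1.47) and naive T cell genes (3 lower, 1 higher of 11, 5 over the list alone; Ccr7 at -1.66). Adjusted p of these 13 lists ran from 1.78e-11 to 0.0323, and from 0.0632 to 0.383 with an estimated correlation. The count was 1134 without NOD NK array 2, 1202 without B6g7 NK array 2 and 1269 without B6g7 lymph node array 2.

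Over all 12 comparisons, 24 lists passed in at least 1. The remaining 5 passed in none; their smallest adjusted p were 0.0621 for chemokine receptors, 0.0645 for immediate early and stress genes, 0.0675 for sex-linked genes, 0.140 for oxidative phosphorylation and 0.209 for islet endocrine genes.

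Markers of other tissues stood out in single arrays. Alb, the albumin gene of hepatocytes, was at 12.71 (log2) in NOD pancreatic T cell array 1, 12.06 in B6g7 pancreatic T cell array 1, 11.71 in B6g7 lymph node array 1, 10.58 and 10.46 in B6g7 infiltrate arrays 1 and 2, and 8.40 in NOD lymph node array 1. The remaining arrays lay between 4.01 and 4.90. Alas2, of erythroid heme synthesis, was at 9.63 in NOD infiltrate array 1. Xist, expressed in female cells, was at 3.72, 4.31 and 7.56 in B6g7 and at 7.21, 5.68 and 4.11 in NOD infiltrates.

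**Figure D3:**
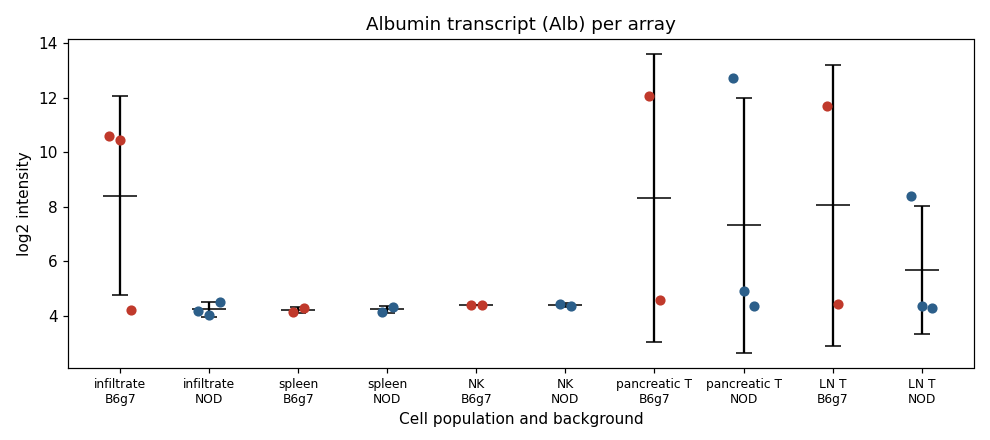
Log2 intensity of Alb (vertical axis) in each of the 24 arrays (points), by group, with group mean and SD (bars). NOD pancreatic T cell array 1 is highest at 12.71, and arrays of the same group lie at 4.90 and 4.35.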

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

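The test of the difference between infiltrate and spleen was planned, and no test in this part was chosen after its result was seen. It passed for 5 probe sets, in log2 units of B6g7 minus NOD. Trgv1 differed by 3.08, at 2.36 in infiltrates and -0.72 in spleen (adjusted p = 0.0124). Ifi209 differed by -2.05, at -0.11 in infiltrates and 1.93 in spleen (adjusted p = 0.0124). A second probe set of the kappa segment Igkv15-103 differed by 1.999, at -0.04 and -2.04 (adjusted p = 0.0224). A kappa segment of the Igkv14 family differed by -1.44, at -0.07 and 1.36 (adjusted p = 0.0185). A probe set without a single named gene differed by 1.26, at 0.24 and -1.03 (adjusted p = 0.0224). Each rests on 3 infiltrate and 2 spleen arrays per background, and immunoglobulin segments can share probe sequences. The count of 5 fell to 0 without B6g7 spleen array 2 or NOD spleen array 1, to 1 without B6g7 spleen array 1, to 2 without NOD spleen array 2 and to 3 without infiltrate array 3 of either background.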

How the results depend on the processing

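Leaving out arrays with liver transcripts or the pancreatic NOD T cell arrays, the liver covariate, the estimated correlation, the serial code block for single genes and the alternatives for the NK list and for the average over populations were tests chosen only after results were seen. Counts below are probe sets passing, against main counts of 34 between infiltrates, 9 between spleens, 5 in their interaction, 18 and 16 between pancreatic and lymph node T cells, 0 and 2 between sites in B6g7 and NOD, 0 in the site interaction, 6 between NK cells, 942 and 1133 for infiltrate against spleen in B6g7 and NOD, and 1882 for NK against T cells.

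With array weights the counts were 302 between infiltrates, 66 between spleens, 18 in the interaction, 0 in pancreatic T cells, 0 between NOD sites, 67 in NK cells, 4283 and 3027 for infiltrate against spleen and 3442 for NK against T cells. Among B6g7 infiltrates array 2 had a weight of 6.078, against 0.588 and 0.601 for arrays 1 and 3. With only the compared groups 29 passed between infiltrates, and 14 of them were among the main 34, so most main calls were lost there. In that setting the counts were 50 between spleens, 2 in the interaction, 0 in pancreatic T cells, 2 in lymph node T cells, 0 between NOD sites and 0 in NK cells. Without dim probe sets they were 2, 1, 1 and 1 for spleen, interaction, NOD site and NK cells. With 1 probe set per gene they were 5, 2, 10 and 3 for spleen, interaction, lymph node T cells and NK cells, and 613 and 663 for infiltrate against spleen. Centring and a trended robust prior each gave 4 between NOD sites. A replicate block gave 307 in pancreatic and 9 in lymph node T cells, and 572 and 732 for infiltrate against spleen.

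The serial code block left 15 between infiltrates, and the liver covariate gave 46. Without the liver arrays 2 passed between infiltrates, 3 in pancreatic T cells, 1 in lymph node T cells and 0 between NOD sites. Without the pancreatic NOD T cell arrays 54 passed between infiltrates, 18 between spleens and 12 in NK cells. Lists passing fell from 94 to 8 with an estimated correlation, and were 101 with probe sets averaged, where 11 of all 348 list tests changed side. Of the tests that passed both with and without averaging, 0 had opposite directions. The NK signature shift of 0.37 was 0.12 with members at least 1 log2 unit higher and 0.13 when chosen against T cells alone.

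Leaving out each array in turn gave 16 to 44 between infiltrates, 6 to 7 between spleens, 0 to 5 in the interaction, 3 to 119 in pancreatic and 1 to 14 in lymph node T cells, 0 between B6g7 sites, 0 to 1849 between NOD sites, 0 to 1 in the site interaction, 3 to 13 in NK cells, 324 to 829 and 351 to 879 for infiltrate against spleen, 1134 to 2055 for NK against T cells, and 94 to 181 for the average over populations (145). The NK signature shift ran from 0.22 to 0.50 and the NK list shift from 0.38 to 0.61. A group left with 1 array was assumed to vary like the others.

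Signs reversed for 3 genes between infiltrates, none of them past the threshold. Cd3e was 0.20 without the liver arrays and 0.12 with the liver covariate, and -0.28 to 0.19 with each array left out. Tnf was -0.11 with the serial code block and -0.11 to 0.14 with each array left out, and Ncr1 -0.046 to 0.41. Among values of single genes outside the leave-one-out settings, 465 kept direction and side of the threshold, 13 newly passed and 77 no longer passed. Leaving out single arrays gave 745, 21 and 127.

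Of the 10 splits of the 6 infiltrate arrays into 3 and 3, 2 called at least 34 probe sets, the real one with 34 among them. The highest other, with 50, followed a run of serial codes, and the real comparison blocked by run called 15. A share under 0.1 cannot arise from 10 splits. For NOD sites, the real split with 2 was 1 of 4 that part all 3 pairs, with 0 the highest of the others, and 4 splits are too few as well. Another split, parting 1 pair, called 114, which points to a structure of the samples beyond site.

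In NOD T cells replicate numbers were taken to pair the samples, although the ages of number 2 differ between sites. The pair as a block gave 3 probe sets against 2 and changed no list call. Elsewhere the correlations did not settle whether numbers pair samples. Between infiltrates, array 2 correlated more with another number (0.0130), and in groups of 2 arrays the deviations mirror each other. In B6g7 T cells the same-numbered arrays of the sites also share age (25 and 22 days), and both arrays 1 carry liver and acinar transcripts; the block left 0 passing by limma there, as without it (81 at an unadjusted p under 0.05). Deviations of same-numbered arrays correlated at 0.42, 0.0033 and 0.55 between infiltrates, 0.65 and 0.22 between pancreatic T cells, -0.04 and 0.29 between lymph node T cells, 0.46 between spleens, 0.65 between NK cells and 0.79 between B6g7 sites.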

Other observations

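The contrast of backgrounds averaged over populations with its alternatives, the test on probe sets of the same gene, the comparison of the liver excess with other sets of arrays, the 2 tests of alternatives to more NK cells (shared splenic difference, T cell expression) and the test of background or site for liver transcripts were chosen only after the results were seen. Averaged over the 5 populations, 145 probe sets differed between backgrounds, 98 higher and 47 lower in B6g7, among them 105 genes. The NOD T cell arrays were taken as paired by number. With same-numbered T cell arrays averaged over the sites in both backgrounds 111 passed, 104 of them among the 145. The count was 94 without B6g7 spleen array 1. Pdk1 was 4.73-fold higher (log2 2.24, SE 0.19, adjusted p = 3.95e-06), from 1.80 in spleen and NK cells to 2.85 in pancreatic T cells. Gm11346 (at least 4.49-fold, adjusted p = 3.95e-06), Tmem14c (4.19-fold, adjusted p = 4.49e-05) and Cd8b1 (5.66-fold, adjusted p = 0.00346) were higher in all 5 populations, with adjusted p of 7.04e-05, 1.87e-04 and 0.0366 after that averaging. Hars, the histidyl-tRNA synthetase (-1.51, SE 0.17, adjusted p = 7.34e-05), Med1 (-1.31, adjusted p = 0.00119) and Erdr1 (-1.15, adjusted p = 0.00209) were lower in all 5. Cd72 passed as well, but lay at the level of absent transcripts in 7 of 10 groups, so no average fold is given. Klra3, Klrd1, Mff, Ly6d, Hat1, Atp6v1d, Srp9, Slc1a5, Emp1, Ifi202b and Tnfrsf1b, named between infiltrates, also passed in this average. Trgv1, Itgae, Ccr2 and Adamdec1 did not. After averaging over the sites Klra3 (adjusted p = 0.0589), Ly6d (0.0604) and Klrd1 (0.1275) no longer passed. The infiltrate arrays are part of the average. These genes were picked after their values were seen.

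Transcripts of hepatocytes stood out in 6 arrays, of which the 5 highest for Alb were tested; the sixth, NOD lymph node array 1, had Alb at 8.40 and Fabp1 at 6.34. Over 61 liver genes not looked at before, the excess over the median of the remaining arrays averaged 2.44 in NOD pancreatic T cell array 1, 1.16 in B6g7 pancreatic T cell array 1, 0.81 in B6g7 lymph node array 1, and 0.39 and 0.37 in B6g7 infiltrate arrays 1 and 2. The excess was alike across genes, with a median pairwise correlation of 0.83 (0.77 to 0.95), against at most 0.53 in 8568 sets of 5 arrays without liver transcripts and 0.82 with separate reference arrays for each, which is what liver RNA or cells carried into single samples would give. A property of background or site is argued against by the range of Alb of 8.37 within pancreatic NOD T cells. None of the 61 genes is in any of the 29 lists, 14 are above the median gene in the other arrays, a first list of 30 was drawn after seeing values, and the CD45 and CD4 gates should remove hepatocytes, so how liver RNA entered stays open.

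The NK list was higher in B6g7 infiltrates by 0.50 (SE 0.14, exact permutation p = 0.1, adjusted p = 0.0833 with an estimated correlation), with 2 of 23 members passing, and by 0.29 in B6g7 NK cells themselves. Liver RNA alone raising the list is argued against in T cells. Their arrays highest for Alb had lower NK lists, by -0.17 (SE 0.05). That SE treats the 4 T cell groups as separate, although the NOD sites were taken as paired. The CD4 gate should remove NK cells, so liver leukocytes in the CD45-gated infiltrates stay untested. In B6g7 infiltrates the list mean was 5.82 and 5.84 in arrays 1 and 2, which carried liver transcripts, and 6.00 in array 3. Expression in the clonotype-high T cells is argued against as well, for the list as a whole. The shift in pancreatic T cells minus that in infiltrates was -0.69 (SE 0.23). Of the 2 members that passed, Klra3 was at -0.42 and Klrd1 at 0.89 in pancreatic T cells. A difference shared by splenic leukocytes cannot be told apart, since the infiltrate shift exceeded that of spleen by 0.29 (SE 0.15), under 2 standard errors. More NK cells in aggressive infiltrates may be kept only as a hypothesis that no test here decides. Higher expression per NK cell, other T cells with NK receptors (Trgv1 and Itgae rose too), age, sex and RMA notes stay untested. A strain variant under the probe sets of NK receptors stays untested too. Klra3, Klrd1, Klra7 and Klrb1a passed between backgrounds in the average over populations, infiltrates included. With T cell arrays averaged over the sites, Klra3 (adjusted p = 0.0589), Klrd1 (0.1275) and Klra7 (0.1721) no longer passed, while Klrb1a did (0.0133).

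Differences shared by the populations of a background could reflect expression or a strain variant under a probe set. Of 38 other probe sets of the genes called, 25 (65.8%) had the same sign and 2 were also called. A variant and a true difference cannot be told apart from these, since a variant lowers 1 probe set and leaves others free. Both stay open for Pdk1, Gm11346 and Cd72, and for the NK receptor genes Klra3, Klrd1, Klra7 and Klrb1a.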
